A study of Drosophila melanogaster with 4 samples.

How the data were processed

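NURF301 is the largest subunit of NURF, a chromatin remodelling complex that slides nucleosomes with the ATPase ISWI. Its binding was mapped by chromatin immunoprecipitation with sequencing (ChIP-seq), in which cross-linked chromatin is pulled down with an antibody and the recovered DNA is sequenced beside the starting chromatin, the input. Per the labels, the chromatin came from wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h, fixed with 1.8% formaldehyde and incubated for 15 h with the NURF301 antibody Q2602. There were 4 samples, 2 ChIP libraries and 2 inputs, and the labels pair input replicate 1 with ChIP replicate 1 and input replicate 2 with ChIP replicate 2. The labels do not say that the replicates came from separate collections of embryos, so the spread between them may be technical only.

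The deposited data used here are 3 lists of regions of significant enrichment, one per ChIP replicate and one combined list for the replicate set. Bowtie 0.12.7 is named in the submitters' processing notes. The program that called the regions, its threshold and the way the replicates were combined are not given in the sources used here. Coordinates are on FlyBase r5, per the file headers, which also give the length of each chromosome sequence. They are printed as the lists give them, counted from 1. Total read numbers of the libraries are not in the lists, so sequencing depth is known only inside the regions.

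Each region carries a deposited score that was read here as a log2 ratio of read counts, from the values themselves. When 2 to the power of the score was divided by a constant for each list (0.885 in replicate 1, 0.927 in replicate 2 and 0.908 in the combined list), 100% of the regions gave a fraction of whole numbers with a denominator of at most 3000, at a relative tolerance of 2e-10. With a wrong constant the share was 0.538%, 0.0949% and 0.146%. The fractions are known in lowest terms only. A pair of counts was recovered for each region by choosing the multiple whose denominator per kb lay closest to the list's typical density on the X, on chromosome 4 or on the autosome arms. Regions of U and the heterochromatic sequences took the autosome density, which is an approximation. The numerators were taken as ChIP counts and the denominators as input counts, an assignment that the files do not state, and whether a small number was added before division is not given in the sources used here. In replicate 1 the median region held 400.5 ChIP counts and 216 input counts, in replicate 2 it held 516 and 282, and in the combined list 799 and 484. The counting error of a score had a median of 0.12 in replicate 1, 0.11 in replicate 2 and 0.083 in the combined list, on the log2 scale. Wilson intervals and counting errors given here cover counting error only.

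The main set consisted of combined-list regions that overlapped a region of each replicate by 1 bp or more. Overlap between the replicate lists was compared with 1000 circular shifts of one list along each chromosome sequence (permutation test, one-sided, smallest possible p 0.001), and Wilson intervals at 95% are given for shares. Scores were compared over reciprocal best overlapping pairs by Spearman's rho and Pearson's r, with intervals from 500 bootstrap draws of 1-Mb blocks. Regions are not independent replicates, and no p is given for these correlations. The X was compared with the large autosome arms 2L, 2R, 3L and 3R by permuting 500-kb windows (100000 resamples, two-sided, smallest possible p 1e-05), with intervals from the spread between windows. A window needed 5 regions to enter a comparison of median scores. Regions of 1 replicate only were compared with shared regions by permuting their status across regions (100000 resamples). Benjamini-Hochberg adjustment was applied to the X comparisons over the main set and the deposited lists, and to the single autosome arms. It was also applied to chromosome 4 and the heterochromatic sequences, and to the differences between paired scores. A p-value not called adjusted is unadjusted.

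The comparisons, their tests and the rule for named regions were fixed before the data were examined. The rule took the 10 highest-scoring and the 5 widest regions of the main set, by coordinates. Comparisons of scores between the X and the autosome arms, and of single autosome arms, chromosome 4 and the heterochromatic sequences (10000 resamples each), were added after the data had been examined. Alternatives were a stricter score threshold, merging of regions closer than 500 bp, a 50% reciprocal overlap, a tolerance of 500 bp, windows of 200 and 1000 kb, the large arms alone, and each replicate list or the whole combined list in place of the main set. Planned comparisons with genes, promoters, gene lists and sequence motifs were left out, because no gene annotation or genome of FlyBase r5 was used here, and regions are therefore named by position alone.

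The overlap test, the window test and the recovery of counts were tested on simulated data. Simulated lists with 60% of 5576 regions copied overlapped at 68.2%, against 19.7% by chance, and independent lists at 20.2%. At a simulated X density 1.3 times that of the autosome arms, 100% of 50 lists passed p 0.05, and at a factor of 1, 8% did. These simulated regions were placed at random without clustering. Real counts of the combined list in 200-kb windows had a variance 2.32 times their mean. The simulated shares therefore do not give the power or the error rate of the window test for clustered regions. For simulated scores of replicate 1, both counts were recovered exactly in 85.2% of regions, and an X to autosome ratio of input density of 0.75 was found as 0.759. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.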

Results

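NURF301 binding was profiled in late embryos, at an age when organs are differentiating, as lists of regions where the ChIP signal exceeded the input. NURF301 was enriched at regions spread over every major chromosome arm. Replicate 1 contained 5576 regions covering 13.1 Mb and replicate 2 contained 6320 regions covering 16.0 Mb, a mean of 5948 ± 526 regions (SD, n = 2). Regions had a median width of 2175 bp in replicate 1 and 2265 bp in replicate 2. The median score was 0.69 in replicate 1 and 0.73 in replicate 2, on the log2 scale, which is 1.62 and 1.66 times the input after the scaling of each list. Of the sequence in the large arms X, 2L, 2R, 3L and 3R, 10.7% was covered in replicate 1 and 13.1% in replicate 2.

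The combined list was longer, with 8224 regions that covered 20.1 Mb and 16.4% of the large arms. Its median score was lower, at 0.53, and its narrowest region measured 1001 bp against 1301 bp in both replicate lists. It included 99.6% of the regions of replicate 1 and 99.6% of those of replicate 2. The main set, combined-list regions present in both replicates, held 5069 regions with a median width of 2603 bp, a median score of 0.72 and 12.3% of the large arms.

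The strongest binding was found on several chromosomes rather than on a single arm. The highest score of the main set, 2.05, belonged to a 2319-bp region on the unplaced sequence U at 4251870 to 4254188, where the replicates gave a mean of 2.04 ± 0.068 (SD, n = 2). It ranked 1 by score in replicate 1 and 3 in replicate 2. On the large arms, the highest score was 1.81, on 2R at 18797646 to 18800778, with a replicate mean of 1.90 ± 0.22 (SD, n = 2). Of the 10 highest-scoring regions, 3 lay on 3L, 2 on 3R, 1 on 2R, 1 on the X, 1 on U, 1 on 3RHet and 1 on 2RHet, and none lay on 2L, which had 6 of the 100 highest-scoring regions against 25 on 3R, 23 on 2R, 23 on 3L and 18 on the X.

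Among the other strong sites, the 3RHet region at 1767336 to 1770302 scored 1.79 and the 2RHet region at 368748 to 371798 scored 1.75. On 3R, the region at 26911068 to 26913666 scored 1.74 and the region at 4838542 to 4842468 scored 1.72. The strongest region of the X, at 10365678 to 10370032, scored 1.74, with 1.60 in replicate 1 and 1.88 in replicate 2. On 3L, a pair of strong regions lay close together near the start of the arm, at 198032 to 201458 with a score of 1.70 and at 245274 to 249280 with a score of 1.73. The third on that arm, at 6734168 to 6738102, scored 1.67. Each of these 10 regions was found as a single region in both replicates.

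The widest binding domains were a different set of places. The widest, on the X at 9048548 to 9060426, spanned 11879 bp with a score of 0.90. The second, also on the X, at 510080 to 520696, spanned 10617 bp and scored 0.71. The other members were on 2R at 6692246 to 6702432 (10187 bp, score 0.89), on 3L at 3217664 to 3227554 (9891 bp, score 1.41) and on 3R at 4871844 to 4881638 (9795 bp, score 0.61). The 3L domain combined great width with strong enrichment, ranking 122 by score in replicate 1 and 91 in replicate 2. In replicate 1, both X domains and the 3R domain were split into 2 regions each, and in replicate 2 the X domain at 510080 to 520696 was split into 3.

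The replicates were then compared to ask how far the same places were bound in both. Most regions were shared, and nearly every strong one was. Of the 5576 regions of replicate 1, 5247 overlapped a region of replicate 2, or 94.1% (Wilson interval 93.5% to 94.7%), against 23.5% under circular shifts (permutation test, one-sided, p = 0.001, the smallest possible). Of the 6320 regions of replicate 2, 5134 overlapped a region of replicate 1, or 81.2% (80.3% to 82.2%), against 20.7% under shifts (permutation test, one-sided, p = 0.001, the smallest possible). In the highest score quartile, 99.5% of the regions of replicate 1 and 98.9% of those of replicate 2 were shared, and in the lowest quartile 86.4% and 49.4%. The midpoints of paired regions lay a median of 76 bp apart.

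Enrichment at shared regions followed the same order in both replicates. Over 5115 pairs, Spearman's rho of the scores was 0.83 (block bootstrap interval 0.82 to 0.84) and Pearson's r was 0.85, both across regions, which are not independent replicates. Widths were also similarly ordered, with a rho of 0.78. Replicate 2 had slightly higher scores, by a median of 0.085 on the log2 scale, or 6.07%, and was higher in 71.0% of pairs. Its paired regions were a median of 165 bp wider. After this median shift was removed, the robust SD of the difference between replicates was 0.15, against a median counting error of 0.16. With a normal approximation for each pair's counts, 0 pairs differed at an adjusted p under 0.05, and 221 (4.32%) had an unadjusted p under 0.05. At this depth, no single shared region could be called different between the replicates.

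**Figure D1:**
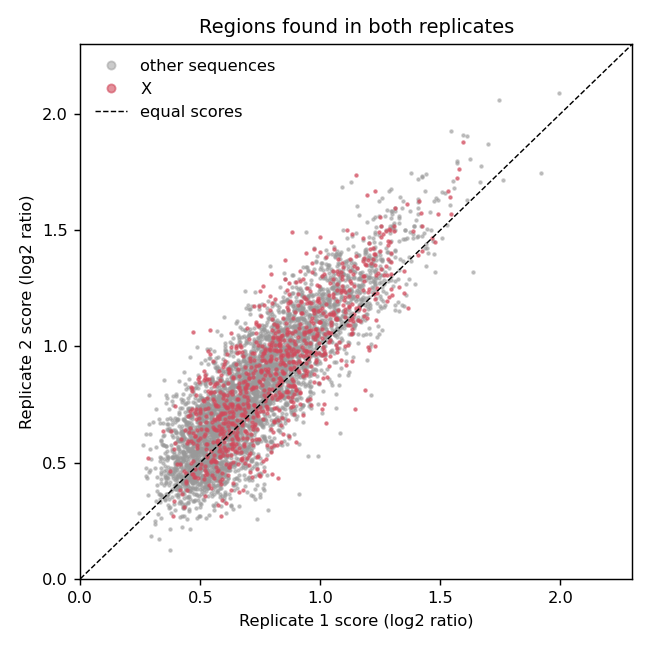
Score of each region in replicate 1 (x axis) against its best overlapping region in replicate 2 (y axis), both as log2 ratios, with 1 point per pair, X regions in red and the dashed line marking equal scores. The 5115 pairs follow the line with a Spearman's rho of 0.83 and lie mostly above it, 71.0% of them being higher in replicate 2.

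Regions found in 1 replicate only were weaker and narrower than shared ones. Weak regions are more easily missed by the other list, and narrow ones overlap less easily, so this direction follows at least partly from selection. Regions are not independent replicates, so the p-values describe these lists only. In replicate 1 there were 329 such regions (5.90%), with a median score of 0.54 against 0.71 for shared regions, a difference of -0.17 (permutation test across regions, two-sided, p = 1e-05, the smallest possible). Their median width was 1517 bp against 2205 bp (permutation p = 1e-05). In replicate 2 there were 1186 (18.8%), with a median score of 0.48 against 0.80, a difference of -0.32 (permutation p = 1e-05), and a median width of 1772 bp against 2393 bp (p = 1e-05). Of the replicate 2 group, 1162 regions (98.0%) were nevertheless present in the combined list, as were 308 (93.6%) of the replicate 1 group. Unplaced sequence had the highest share, with 8 of 27 U regions of replicate 1 (29.6%) and 9 of 28 of replicate 2 (32.1%) found in that replicate only.

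By median score, combined-list regions outside the main set were weaker than those in it, a direction that selection by the replicate lists would also give. Of its 8224 regions, 5069 (61.6%) overlapped both replicates, 297 replicate 1 only, 1138 replicate 2 only and 1720 (20.9%) neither. The median score was 0.72 for those in both replicates, 0.34 and 0.36 for those in replicate 1 or replicate 2 only, and 0.36 for those in neither. Regions in neither replicate had a median width of 1267 bp. The very highest scores went the other way. Of the 50 highest-scoring combined-list regions, 37 overlapped neither replicate and 13 overlapped both.

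The distribution over chromosomes was compared next. NURF301 regions were dense on all euchromatic sequences, including the small chromosome 4, and sparse in the assembled heterochromatin. These densities are per Mb of listed sequence, and the lists do not tell how much of it unique reads can map. Density ranged from 45.9 ± 3.78 regions per Mb on 2L to 55.1 ± 4.98 on 2R (SD, n = 2), with 46.1 ± 4.06 on 3L, 50.2 ± 4.66 on 3R and 46.8 ± 4.32 on the X. Chromosome 4, which carries much heterochromatin-like chromatin among its genes, had 42.2 ± 2.09 regions per Mb. The 6 heterochromatic sequences together had 6.52 ± 0.38 and U had 2.74 ± 0.070. XHet stood apart from the other heterochromatic sequences at 46.5 ± 3.46 regions per Mb, from 9 regions in replicate 1 and 10 in replicate 2 on 0.204 Mb. The replicate lists held 0 regions on YHet and 0 on Uextra.

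**Figure D2:**
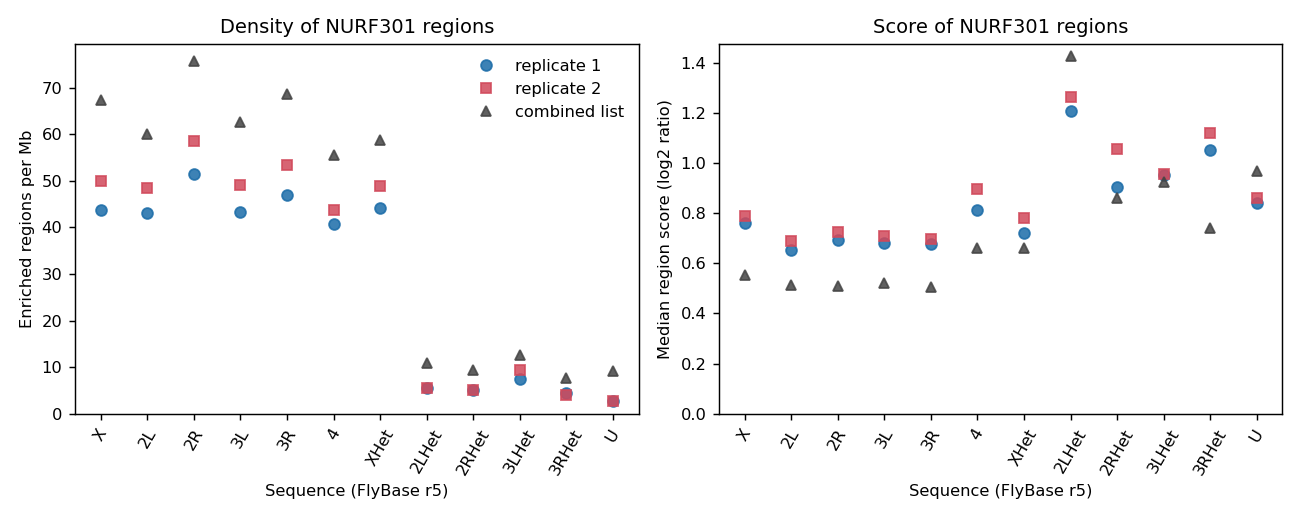
Regions per Mb (left) and median region score as a log2 ratio (right) on each chromosome sequence, with circles for replicate 1, squares for replicate 2 and triangles for the combined list. The large arms, chromosome 4 and XHet lie at or above 40.7 regions per Mb in both replicates, and the other heterochromatic sequences and U lie at or below 9.39 regions per Mb in both replicates.

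Among the autosome arms, 2R had the highest density of regions. In 500-kb windows, 2R averaged 51.7 regions per Mb against 44.6 on the other autosome arms in replicate 1 (permutation test, two-sided, adjusted p = 0.0432 over 4 arms) and 58.8 against 50.5 in replicate 2 (adjusted p = 0.0356). In the combined list the values were 76.0 and 64.1 (permutation test, adjusted p = 0.00240). In the main set 2R had 47.2 against 40.7, which did not pass (permutation test, adjusted p = 0.0528). The combined list also had fewer regions on 2L, 60.1 against 68.8 (permutation test, adjusted p = 0.0206), a difference that did not pass in replicate 1 (adjusted p = 0.212), in replicate 2 (adjusted p = 0.187) or in the main set (adjusted p = 0.237).

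**Figure D3:**
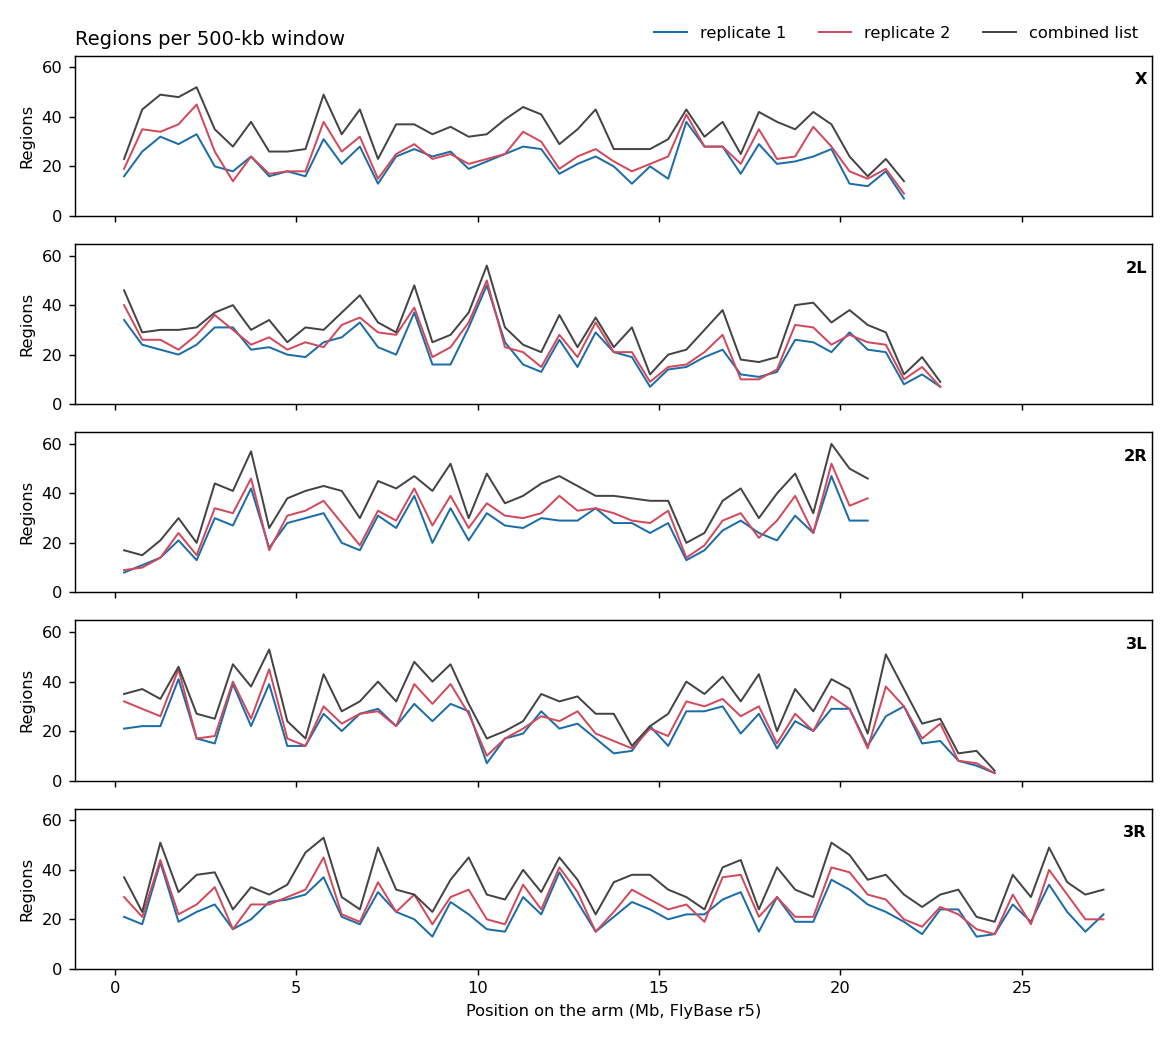
Number of regions in each 500-kb window (y axis) along the large arms in Mb (x axis), with lines for replicate 1, replicate 2 and the combined list. The lines rise and fall together, with a Spearman's rho of 0.938 between the replicates over 593 windows of 200 kb.

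The X did not differ detectably from the autosome arms in the number of regions, but its regions had higher scores. The main set had 39.9 regions per Mb on the X and 42.1 on the autosome arms, a difference of -2.26 (interval -6.47 to 1.95, permutation test over 44 and 192 windows, two-sided, p = 0.360, adjusted p = 0.639). The median score per window was 0.78 on the X and 0.70 on the autosome arms, a difference of 0.073 (interval 0.041 to 0.105, permutation p = 1e-05, the smallest possible, adjusted p = 1.33e-05), which made the count ratio 5.20% higher. The difference was 0.079 in replicate 1 (permutation p = 1e-05), 0.086 in replicate 2 (p = 1e-05) and 0.047 in the combined list (p = 0.001). The test treats windows as exchangeable, and the X is a single chromosome, so these p-values do not cover variation between chromosomes. An offset of the X between ChIP and input libraries would also raise its scores and cannot be told apart from higher binding here. Among main-set regions with a score at or above the median, the X had 23.6 regions per Mb against 20.0, a difference of 3.65 (interval 0.635 to 6.66, unadjusted permutation p = 0.0129). Higher scores on the X move its regions past this cut by themselves, so this value is not a separate result. Input counts per kb were lower on the X than on the autosome arms, at 75.7 against 101 in replicate 1 and 92.3 against 126 in replicate 2.

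Chromosome 4 and the pooled heterochromatic sequences had higher median region scores than the autosome arms. On chromosome 4 the median score was 0.81 over 55 regions in replicate 1, against 0.68 on the autosome arms (permutation test across regions, two-sided, adjusted p = 0.0028), and 0.90 over 59 regions in replicate 2, against 0.71 (adjusted p = 0.0016). The count ratio there was 10.0% higher in replicate 1 and 14.0% higher in replicate 2. Chromosome 4 regions were also wider, 2533 bp against 2170 bp in replicate 1 (permutation test, adjusted p = 0.0004) and 2515 bp against 2257 bp in replicate 2 (adjusted p = 0.0178). On the heterochromatic sequences the few regions present scored 0.91 in replicate 1 (58 regions, permutation test, adjusted p = 0.0004) and 0.94 in replicate 2 (63 regions, adjusted p = 0.0004). Among these sequences XHet was closest to the autosome arms, with a median of 0.72 in replicate 1 (9 regions) and 0.78 in replicate 2 (10 regions). Permuting regions ignores their clustering along the chromosome, so these p-values are too small to the extent that neighbouring regions resemble each other.

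**Figure D4:**
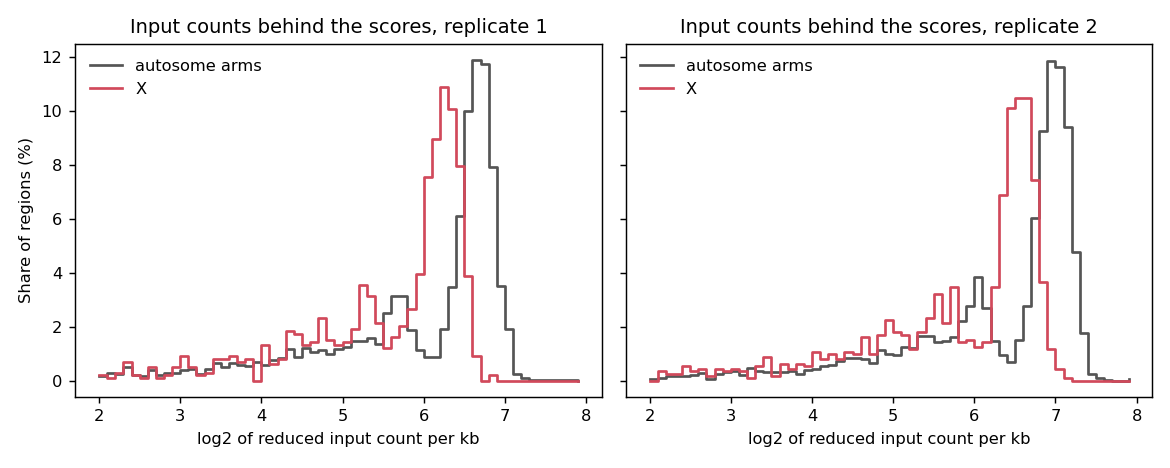
Share of regions (y axis, percent) by the log2 of the input count per kb in lowest terms (x axis), for X regions in red and autosome arm regions in grey, in replicate 1 (left) and replicate 2 (right). The main peak of the X lies to the left of that of the autosome arms in both replicates, at an estimated density ratio of 0.748 and 0.730.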

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

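The tests of the highest-scoring regions and of a uniform offset on the X were chosen after the results were seen. Those of weak regions on the X were not set out beforehand. The other tests in this part were set out before they were run, but the X score comparison was itself added after the data had been examined. The design has a single antibody, strain and age and names no groups in which binding is to differ, so biological explanations stay untested.

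Input counts recovered from the scores are a signal outside the comparisons of regions. Their density on the X was 0.748 of that on the autosome arms in replicate 1 (SE 0.00779) and 0.730 in replicate 2 (SE 0.00693). Chromosome 4 had 1.25 times the density of the autosome arms in replicate 1 (SE 0.0298) and 1.20 times in replicate 2 (SE 0.0227). The lists also held 193 combined-list regions on U and the heterochromatic sequences, outside the comparison of the large arms, of which 93 lay on U. Only 20.4% of the U regions overlapped both replicates.

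Most of the highest scores of the combined list lay on regions found in neither replicate. Its top region, on 2L at 20009924 to 20010926, had a score of 3.67 that stood for 14 ChIP counts over 1 input count in lowest terms, and the top region of replicate 2, on 2RHet at 772364 to 773664, stood for 15 over 1; neither was in the main set. The top region of replicate 1, on U at 4251942 to 4254074, was in the main set and stood for 9 over 2 in lowest terms, but the same site stood for 101 over 22 in replicate 2 and 329 over 72 in the combined list, which are lower bounds of the counts. The 50 highest-scoring combined-list regions had a median input count of 2.5 in lowest terms, against 328.5 for all regions. Of them, 60% lay on U or heterochromatic sequences, against 2.35% of all regions (Fisher's exact test, p = 4.06e-37). While 37 of the 50 overlapped no region of either replicate, 13 overlapped both, among them the 10 highest-scoring regions of the main set. Both a near-absence of input reads and repeated or unplaced sequence are consistent with these values and may act together, since sequence where few reads can be placed gives a small denominator.

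Higher scores on the X were accompanied by fewer weak regions, below the 75th percentile of autosome scores, at 0.822 of the autosome density in the main set (permutation p = 0.00286), 0.829 in replicate 1 (p = 0.00323) and 0.849 in replicate 2 (p = 0.00885), though not detectably in the combined list (0.948, p = 0.315); higher scores move regions across this bound by themselves, so these values do not show a loss of weak regions at the lower input depth. Such a loss is not the whole cause, since it adds no strong regions, and regions at or above that percentile were 1.32 times as dense on the X in the main set (permutation p = 0.00083), 1.37 times in replicate 1 (p = 7e-05) and 1.32 times in replicate 2 (p = 3e-04). For counting error, the X exceeded the autosome arms by 0.293 of the score difference in the combined list. In replicate 1 and replicate 2 the value was 0.207 and 0.182, each under the 0.5 set beforehand. A difference of errors does not give the shift that selection by score would cause, so these ratios cannot decide on it. For a uniform offset of the X between ChIP and input libraries, which would raise all scores alike, the difference at the 90th percentile exceeded that at the 10th by 0.0062 in replicate 1 (block bootstrap interval -0.023 to 0.065), 0.016 in replicate 2 (-0.011 to 0.060) and 0.025 in the combined list (-0.0019 to 0.062). These intervals hold both 0 and values above 0.5 of the median score difference, and signal outside the regions is not in the lists, so an offset and higher binding on the X cannot be told apart.

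Combined-list regions in neither replicate formed the third pattern. Of the 1720 regions, 932 (54.2%) were narrower than 1301 bp, the narrowest region of the replicate lists, so that a lower width limit of the combined list may account for those. The remaining 788 had a median score of 0.32, a difference of -0.399 from regions in both replicates. Regions missed by both replicate lists are weaker by selection, so this value leaves open whether they are weak enrichment that only the pooled reads pass. Over 5064 other combined-list regions, which had replicate counts, combined ChIP counts were a median of 0.965 of the sum of the replicates' counts. Combined input counts were a median of 0.993 of their sum, partly by construction, since denominators were matched to each list's typical density.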

How the results depend on the processing

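The alternatives for the covered share, for X scores, for named regions and for the number of combined-list regions in both replicates, and the overlap of the best-scoring regions with the whole other list, were chosen after seeing the data. Of the 39 alternatives to results of the comparisons, 31 kept direction and side of the threshold where there was a test, or stayed within 1.5 times the count or inside the interval of the rank agreement where there was none. Taking only regions with a score at or above the median left 2788, 3160 and 4112 regions in replicate 1, replicate 2 and the combined list, by construction. The rank agreement fell to a rho of 0.78 with width in place of score. The difference in regions per Mb between the X and the autosome arms, -2.26 in the main set, turned to 1.58 in the whole combined list (permutation p = 0.639) and to 3.65 at or above the median score (p = 0.0129), and lay between -1.73 and -1.72 without replicate 1 or replicate 2. The difference in covered share, -0.132 percentage points, turned to 0.538 (permutation p = 0.551) and 1.42 (p = 0.00454) in the same settings, and lay between -0.209 and -0.0887 without replicate 2 or replicate 1. At or above the median score, the higher scores on the X move its regions past the cut by themselves. For the whole combined list, the cause of the turn was not tested. The higher X score held in all 5 alternatives run, at 0.047 to 0.086. Of the 30 scores or widths of named regions in a single replicate, 11 moved by more than the SD between replicates. Apart from the scores themselves, no paired analysis was possible because no result compares ChIP with input libraries as unpaired groups. As read here, each score already sets a ChIP library against the input of the same replicate, so it is itself a paired value. Input counts are known only inside that replicate's regions, recovered from the same ratio, so they give no comparison apart from the score. Alternatives that need genes, promoters, motifs or regions per gene were not run. Counting error was about as large as the difference between replicates at single regions, so depth limits any comparison there.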

Other observations

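The tests in this part were all chosen after the results were seen. NURF301 regions were sparser at the centromere-proximal end of most arm sequences. Heterochromatic sequences are listed apart from the arms, so these ends need not reach the centromere. In the 2 Mb at that end, the main set had 20.0 regions per Mb on the X against 41.2 on the rest of the arm, 22.5 against 40.6 on 2L, 25.5 against 49.3 on 2R and 16.0 against 42.3 on 3L. On 3R the order was the opposite, 47.5 against 42.2. The mean difference over the 5 arms was -16.8 ± 12.7 regions per Mb (SD), lower in 4 of 5 arms, with an exact permutation p of 0.125 where the smallest possible is 0.0625. How much of the sequence at these ends unique reads can map is not in the lists.

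Regions were also unevenly spaced within the arms. The densest 200-kb window, on 2L from 10200001 to 10400000, held 35 combined-list regions, with 31 regions in replicate 1 and 33 in replicate 2, against a median of 13 per window. The next were on 3R from 11000001 to 11200000 and on the X from 2000001 to 2200000, with 29 regions each. The variance of the window counts was 2.32 times their mean. There were 67 stretches of over 100 kb without a combined-list region on the large arms, against a mean of 3.15 and at most 11 in 1000 random placements (permutation test, one-sided, p = 0.001, the smallest possible). The longest, on 3L from 23337431 to 23572753, measured 235 kb and was followed by 231 kb on 3L from 24225545 to 24456291 and by 221 kb on 2L from 11582809 to 11804241. The lists do not tell how much of such a stretch can be mapped by unique reads.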
